A study of Bos taurus with 15 samples.

How the data were processed

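Messenger RNA was sequenced from bovine endometrial epithelial cells, the lining cells of the uterus. Per the labels' protocols, cells scraped from 4 uteri were pooled, frozen, thawed at passage 3 and grown to 90% confluence. They were then kept for 48 h in wells of one plate per experiment under 3 conditions. In the contact group, in vitro produced morulae of day 5.5, in groups of 15 ± 1, lay on the cell layer. In the no contact group the morulae sat in a transwell insert above the cells. The control group held cells without embryos. Each group has 5 libraries. Because all cells came from one pooled stock, the p-values measure the spread between cultures of that stock and not between cows.

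The table the authors deposited holds one value per gene and library, a signal in the form of read counts divided by one size factor per library. Per the submitters' processing notes the tools were HISAT2 2.1.0, featureCounts 1.6.2 and DESeq2 1.18.1, with no role given for any of them. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, although the labels' protocols call the libraries strand-specific with paired reads of 100 bases. Reads of overlapping or antisense genes and of close paralogs, such as OAS1X and OAS1Y, are therefore uncertain. The same deposited table carries the authors' log2 fold changes, their Wald statistic as a score, and their p-value and FDR per comparison.

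The deposited values were not raw counts. In each of the 15 libraries 100% of the values were whole multiples, within 0.01 of a read, of that library's smallest value above 0, and dividing by it gave back whole reads. The design fixed before the data were examined assumed raw counts and edgeR, and named limma on log2(value + 1) for the case of normalized values. That test is the main one here. It used limma 3.58.1 in R 4.3.3 with a mean-variance trend, robust empirical Bayes, one coefficient per group over all 15 libraries and a pseudocount of 1. Genes needed a normalized count of at least 10 in at least 5 libraries, which left 12559 of 19994 genes, while 3511 genes were listed at 0 in every library. Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts. As an alternative chosen after seeing the data, edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered reads called 930 genes higher and 691 lower in contact than control, 188 and 16 in no contact than control, and 478 and 222 in contact than no contact.

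A total of 17 gene lists with 504 symbols were fixed before the data were examined. They cover interferon-stimulated genes, antigen presentation, inflammation, prostaglandins, receptivity and histotroph, adhesion and junctions, Notch and ephrins, extracellular matrix and TGF-beta, hypoxia and glycolysis, cell cycle, the unfolded protein and amino acid stress response, cholesterol synthesis, and markers of epithelium, stroma, endothelium and muscle, leukocytes and red cells, and the embryo. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Names came from the deposited table for 16378 genes and, through the NCBI gene number, from a RefSeq table of assembly ARS-UCD2.0 for 877, and 2739 genes had no symbol.

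The rule for named genes was also fixed beforehand. It takes, per comparison, the 12 genes with the smallest p in each direction among called genes with a symbol and a mean log2 CPM of at least 0, up to 4 members of each list, and a fixed panel of interferon, prostaglandin and receptor genes. It names 162 genes over the 3 comparisons. All 162 entered the alternatives and the search for outlying libraries, while the genes printed here were picked from them after their values were seen. Some of the named genes are not reported here.

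Reads assigned to genes ranged from 4195091 to 19792557 per library. The labels describe replicate experiments but do not tie a library to one. Library numbers in the titles fall into runs (24 to 30, 83 to 90, 97 alone, and BEEC.103 to 110, BEEC being the title's prefix). The run 24 to 30 holds only control 24, no contact 30 and contact 28, and the only contact library in 83 to 90 is 87. Within-run values there rest on these single libraries. Libraries of different groups in the same run deviated together from their group means, with a median correlation of 0.219 over 23 pairs against -0.0945 over 52 pairs from different runs, and 14 of the 14 libraries with a partner correlated best within their own run. The main fit and the permutation tests of library measures held no term for the run, so their p-values do not allow for it. The run entered as a block in an alternative fit, and within-run or blocked values are printed beside some results. Contact library 97 is alone in its run, so with the block the contact values rest on the other contact libraries. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other size factors, 2 other filters, a fit of only the 2 groups compared, non-robust variances, the run as a block, and each library left out in turn. Alternatives added after seeing the data were edgeR with TMM, TMM factors in limma, pseudocounts of 0.5 and 5, library weights, and fits without libraries that stood apart.

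Library measures were compared with two-sided exact permutation tests. The tests were checked on simulated data: reads were drawn for the real genes and depths, with 100 genes changed 1.5-fold and 100 changed 2-fold. The main test recovered 78% and 95% of them in contact against control (12498 genes fitted), 79% and 95% in no contact against control (12500 genes fitted), and 83% and 91% in contact against no contact (12504 genes fitted). It also called 4, 3 and 11 unchanged genes in these comparisons. The simulated libraries held no effect of the run, so recovery and false calls in the real data may differ. No 2 libraries of a group agreed within sampling noise, since chi-square per degree of freedom was at least 2.407 over 30 pairs. Some neighbouring numbers agreed more closely: control 83 and 84 had 3.235, control BEEC.103 and BEEC.104 2.892, and no contact 109 and 110 3.994. Other pairs had 9.306 to 17.33 in control and 10.21 to 49.55 in no contact, with no contact 89 and 90 at 41.53. Libraries of the same run may therefore not be independent experiments, which the main tests do not allow for.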

Results

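The transcriptome of bovine endometrial epithelial cells was measured in 15 libraries, 5 from cells cultured alone, 5 from cells that shared the well with morulae held in a transwell, and 5 from cells in direct contact with morulae. Assigned reads per library were 15507719 to 18618467 in the control group and 12938091 to 19792557 in the no contact group. In the contact group 3 libraries held 16670801 to 19268029 reads, while libraries 97 and 108 held 4195091 and 6104652. The first principal component carried 46.62% of the variance and placed the no contact libraries between the control and contact libraries. On the second component, with 12.92%, no contact library 90 stood apart at 32.58.

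**Figure D1:**
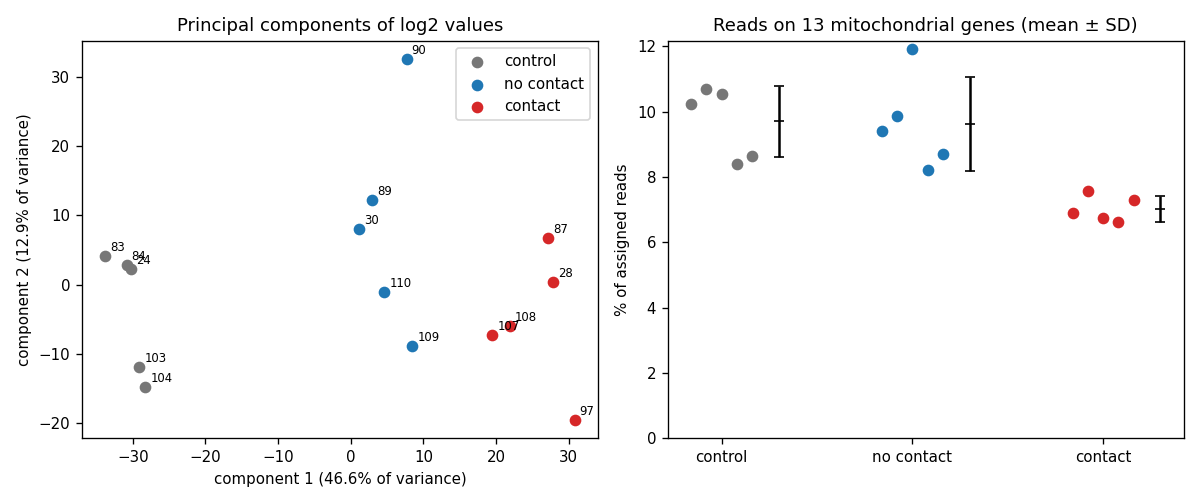
Left, the 15 libraries on the first and second principal components of log2 values, labelled with their library numbers. Right, the percent of assigned reads on 13 mitochondrial genes per library with the group mean ± SD (n = 5); the contact libraries averaged 7.021% and the controls 9.706%.

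The first comparison asked what embryos lying on the cells change. Interferon-stimulated genes, the antiviral genes switched on by type I interferons, were higher in contact than in control for 42 of 42 tested members, with a median log2 fold change of 4.91. MX1, an antiviral GTPase, went from 101.0 ± 24 to 26814 ± 3489 normalized counts (SD, n = 5 per group; log2 fold change 8.06 ± 0.13 SE, limma adjusted p = 1.18e-19). OAS1Y, an enzyme that activates RNase L, rose by 6.42 ± 0.08 (limma adjusted p = 8.51e-23), and ISG15, a ubiquitin-like protein, rose by 8.73 ± 0.30 (limma adjusted p = 1.18e-11). IFIT1, USP18, GBP4, IFI27, IFI44L, UBA7, DTX3L, PARP9 and PARP12 were among the genes with the smallest p. OAS1X, which shares sequence with OAS1Y, rose by 7.44.

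Antigen presentation genes were higher in 16 of 21 members, and in 16 when adjusted over the list alone. All 42 interferon genes also passed when adjusted over the list alone. B2M, the light chain of MHC class I, rose from 3321 ± 283 to 15246 ± 2167 normalized counts (log2 fold change 2.19 ± 0.09 SE). PSMB8, a subunit of the immunoproteasome, rose by 1.43, and the peptide-trimming enzyme ERAP2 by 1.46. The interferon and antigen lists passed camera (adjusted p = 3.18e-147 and 2.01e-22) and also with an estimated correlation (adjusted p = 6.93e-05 and 0.00766). Within the runs of library numbers 24 to 30, 83 to 90 and BEEC.103 to 110, the median change of the interferon list was 5.41, 5.14 and 4.61, and that of the antigen list 1.33, 1.40 and 1.10.

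Cell cycle genes were higher in contact than control in 27 of 32 members, and 31 when adjusted over the list alone, with a median of 0.60. TOP2A, a DNA topoisomerase of dividing cells, went from 416.0 ± 46.9 to 691.6 ± 151 normalized counts (log2 fold change 0.71 ± 0.11 SE, limma adjusted p = 0.000194), and CCNA2, a cyclin of S phase, rose by 0.89. CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 0.66. It was also called lower in no contact against control (log2 fold change -0.33, limma adjusted p = 0.0258), a call lost in 6 fits that left out 1 library. Cholesterol synthesis genes were higher in 15 of 24 members, and 16 when adjusted over the list alone, with HMGCS1 up by 0.57. Both lists passed camera (adjusted p = 3.37e-19 and 6.34e-09) but not with an estimated correlation (adjusted p = 0.135 for each). With fry, which tests whether a list's genes move one way on balance, both passed (adjusted p = 0.000953 for each). Within the 3 runs, the medians were 0.65, 0.76 and 0.44 for the cell cycle and 0.54, 0.38 and 0.13 for cholesterol synthesis.

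Inflammatory genes were lower in 9 of 21 members, also 9 when adjusted over the list alone, and higher in 0. Their median was -0.50, and within the 3 runs -0.60, -0.76 and -0.25. The filter kept 21 of the 35 members measured. CXCL10, IL1B, PTX3, S100A8, S100A9 and M-SAA3.2 were listed at 0 in all libraries, so the list says nothing about them. The neutrophil chemokines CXCL8, CXCL5 and GRO1 fell by 1.38, 1.11 and 0.98. The acute phase gene SAA3 fell by 1.44, a call that was lost without both shallow contact libraries (limma adjusted p = 0.0829). CXCL8 went from 140.7 ± 15.2 to 56.1 ± 21.6 normalized counts (limma adjusted p = 1.19e-05). The list passed camera (adjusted p = 3.13e-05), with adjusted p = 0.135 under an estimated correlation and 0.00249 with fry. Hypoxia and glycolysis genes were lower in 6 and higher in 1 of 32 (7 and 3 adjusted over the list alone), and matrix genes were lower in 4 of 27 (5 adjusted over the list alone). These calls by camera (adjusted p = 0.0119 and 0.0285) were lost with an estimated correlation (adjusted p = 0.357 and 0.387), while both lists passed with fry (0.0231 and 0.0284). The matrix call by camera also ended without contact library 97 (adjusted p = 0.0667) and with the run as a block (adjusted p = 0.0557). CEMIP, which takes part in hyaluronan breakdown, fell from 20631 ± 2711 to 6129 ± 719 normalized counts (log2 fold change -1.75 ± 0.13 SE, limma adjusted p = 2.45e-09).

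Of 12559 genes tested, limma called 901 higher and 726 lower in contact than control, 175 and 46 of them by over 2-fold. Without control library 83 the lower count was 473, and without both shallow contact libraries it was 420. With the run as a block the counts were 1069 higher and 963 lower. A fit of only these 2 groups gave 1174 and 1046, and library weights gave 1125 and 1036. In the table the authors deposited, 986 genes were higher and 811 lower.

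The second comparison asked whether embryos act on the cells across a transwell. The interferon-stimulated list was again higher in 42 of 42 members, also 42 when adjusted over the list alone, with a median of 3.81, and within the 3 runs of 3.38, 3.86 and 3.66. MX1 reached 11972 ± 1458 normalized counts (log2 fold change 6.90 ± 0.13 SE, limma adjusted p = 2.34e-18), and ISG15 rose by 7.64 and IFI6 by 6.76. Antigen presentation genes were higher in 10 of 21 members, and 15 when adjusted over the list alone, with B2M up by 1.31 and PSME1, an activator of the proteasome, up by 0.82. The antigen list had medians of 0.47, 0.75 and 0.62 within the 3 runs. Both lists passed camera (adjusted p = 8.32e-280 and 1.68e-23), also with an estimated correlation (adjusted p = 1.96e-06 and 0.00634).

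In the cell cycle list limma called 0 of 32 members, also 0 when adjusted over the list alone, with a median of -0.05, and in the cholesterol list 0 of 24, also 0 over the list alone, with a median of 0.04. In both lists 0 members had an unadjusted p under 0.05 with limma, and DESeq2 and edgeR also called 0. Neither list passed camera (adjusted p = 0.712 and 0.299), but without no contact library 90 the cell cycle list was called lower (0.0399). TMEM107, a protein of the ciliary transition zone, went from 87.7 ± 6.12 to 30.2 ± 7.0 normalized counts (log2 fold change -1.53 ± 0.19 SE, limma adjusted p = 1.25e-05), and the mitochondrial ornithine carrier SLC25A15 fell by 0.57. Camera called the inflammatory, adhesion and matrix lists lower (adjusted p = 0.0361, 0.0244 and 0.0244). In these lists 0 of 21, 1 of 29 and 0 of 27 members were lower (0, 2 and 0 adjusted over the list alone; 3, 6 and 3 at an unadjusted p under 0.05; 0, 1 and 1 with DESeq2; 0, 1 and 0 with edgeR), and with an estimated correlation the lists had adjusted p = 0.668 each. The inflammatory call was lost without control 24 (0.178), 83 (0.0535) or 84 (0.198) or no contact 109 (0.388) or 110 (0.152), the adhesion call without control 24 (0.108) or no contact 90 (0.173) or 110 (0.0935), and the matrix call without control 24 (0.0577) or 83 (0.0535) or no contact 90 (0.0653), 109 (0.0502) or 110 (0.116).

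limma called 186 genes higher and 14 lower in no contact than control. The lower count was 3 without control library 83, 6 without control library 24 or 84, 5 without no contact library 90 and 8 without no contact library 110. With the run of library numbers as a block the counts were 244 higher and 52 lower. The table the authors deposited holds 203 higher and 27 lower.

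All of the 186 genes called higher without contact were also called higher with contact, and 13 of the 14 lower genes were also lower. The shared lower count was 3 without control 83, 5 without control 84, 6 without control 24, 5, 6 and 8 without no contact 90, 109 and 110, and 43 with the run as a block. Independent lists of these sizes would share 13.3 and 0.809 genes. Unchanged groups simulated 50 times against the 5 controls shared 0 in each direction, which sets no bound, since unchanged groups have few calls to share and were drawn without the runs. With separate controls for the 2 comparisons, over the 10 ways of splitting the controls and both ways round, 119 to 149 genes were shared upward and 1 to 8 downward. Over all genes the log2 fold changes had the same sign in 67.6%, against 66.6% simulated from shared controls alone, a correlation of 0.876 against 0.501 and a covariance of 0.154 against 0.011.

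The third comparison tested contact directly against no contact. Interferon-stimulated genes were higher with contact in 40 of 42 members, and 41 when adjusted over the list alone, by a median of 0.94, and within the 3 runs by 1.31, 0.97 and 0.78. MX1 was higher by 1.16 ± 0.13 SE (limma adjusted p = 1.23e-05) and IFIT2 by 2.95, from 261.2 ± 62.7 to 2094 ± 875 normalized counts. ISG15 had 4250 to 6831 normalized counts in contact and 1944 to 3262 in no contact, without overlap. The spread in its test was pooled with that of the controls, which had 6.263 to 24.43. The call of ISG15, at 1.08, was marginal (limma adjusted p = 0.0481). It was lost in 12 of the 15 fits that left out a library (all but those without control 24, 83 or BEEC.103), with an adjusted p of 0.0552 to 0.107 there, and with the run as a block (0.0724). MX2, another antiviral GTPase, had 0.677 ± 0.690 normalized counts in control, 54.0 ± 28.8 in no contact and 1679 ± 1121 in contact. Antigen presentation genes were higher in 12 of 21 members, and 16 when adjusted over the list alone, with B2M up by 0.88 and medians within the 3 runs of 0.81, 0.51 and 0.44. Both lists passed camera (adjusted p = 1.23e-70 and 1.96e-14), also with an estimated correlation (adjusted p = 0.00253 and 0.0402). ATP8B4, FOXS1, CMPK2 and TNFSF10 were also higher.

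Cell cycle genes were higher with contact in 24 of 32 members (32 adjusted over the list alone), by a median of 0.63, and cholesterol synthesis genes in 10 of 24 (15, with 1 lower, over the list alone), by 0.28. Within the 3 runs the medians were 0.54, 0.72 and 0.53 for the cell cycle and 0.41, 0.39 and 0.10 for cholesterol synthesis. With an estimated correlation these lists had adjusted p = 0.0710 and 0.125. Inflammatory genes were lower in 3 of 21 members (6 adjusted over the list alone), CXCL8, CXCL5 and GRO1, at -1.20, -0.73 and -0.72 (list adjusted p = 0.236 with an estimated correlation), and the list's medians within the 3 runs were -0.26, -0.46 and -0.02. Camera gave these 3 lists adjusted p = 2.57e-28, 8.75e-10 and 0.000425, and fry gave 0.000894, 0.00293 and 0.0709. The call of CXCL5 was lost without no contact 30 (0.0595) or 90 (0.0691) or contact 97 (0.0557) and with the run as a block (0.0526), and that of GRO1 without no contact 30 (0.0740) or 110 (0.0630) or contact 28 (0.0687) or 87 (0.0604). CEMIP was lower by a log2 fold change of -1.19, and PDK2, a kinase that restrains pyruvate dehydrogenase, of -0.48.

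Transcripts of the mitochondrial genome took 7.021% ± 0.395 of reads in contact, 9.622% ± 1.42 in no contact and 9.706% ± 1.09 in control (SD, n = 5). Contact differed from each other group (exact permutation p = 0.00794, 0.0298 after Benjamini-Hochberg over 15 tests), with each contact library below each of the other 10. The share of reads on the 10 most abundant genes moved with it, at 12.57% ± 0.510 in contact, 14.2% ± 0.566 in no contact and 14.89% ± 0.636 in control (the same exact permutation p and adjusted value). Within the 3 runs the mitochondrial difference was -3.35, -3.04 and -1.58 percentage points against control and -2.50, -3.32 and -1.52 against no contact. Of 13 mitochondrial genes, 12 were lower in contact than control and 10 lower than in no contact, among them CYTB at -0.84 against no contact.

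limma called 469 genes higher and 229 lower in contact than no contact. The lower count was 115 without contact library 97, 142 without 28 and 145 without 87, and it was 116 without no contact library 30, 131 without 89 and 349 without 109. Fitting only these 2 groups gave 111, blocking on the run gave 344, and leaving out both shallow contact libraries gave 306 higher and 84 lower. The table the authors deposited holds 571 higher and 328 lower.

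**Figure D2:**
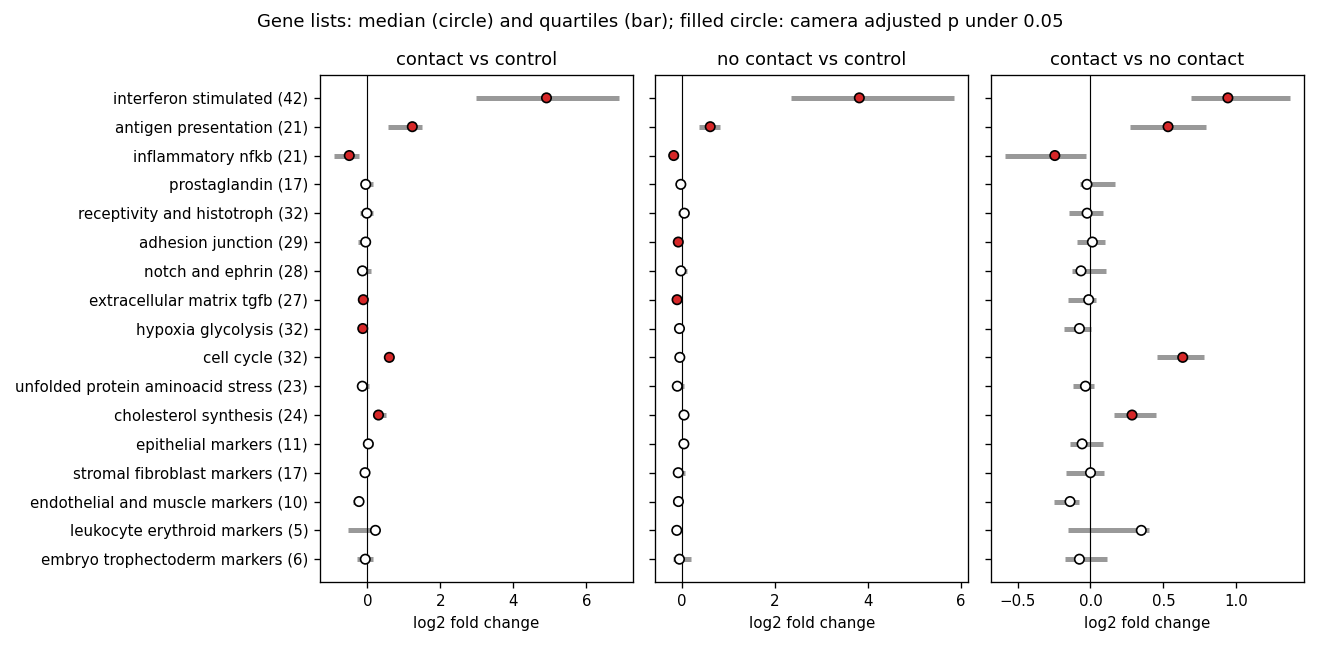
Median (circle) and quartiles (bar) of the log2 fold change over the tested members of each gene list, with the number of members in brackets, for the 3 comparisons; filled circles mark camera adjusted p under 0.05, and the horizontal axes differ in scale. The interferon-stimulated list lies at 4.91, 3.81 and 0.94.

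**Figure D3:**
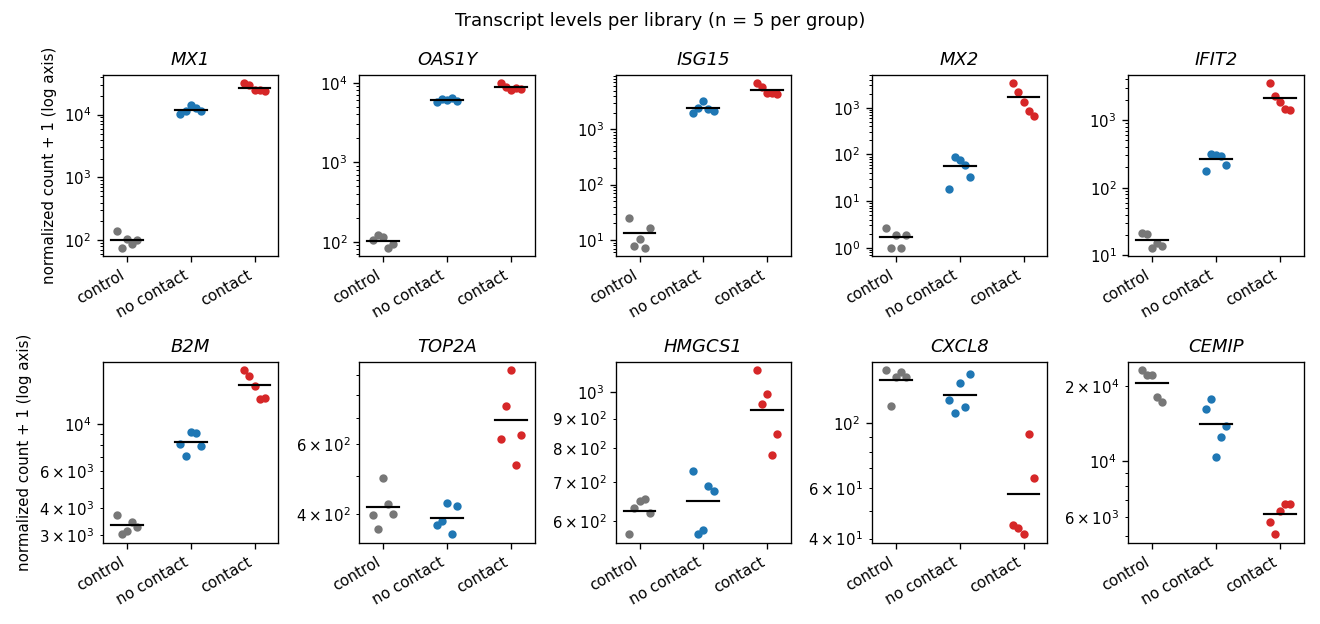
Normalized count + 1 on a log axis for 10 genes, one point per library and a line at the mean of 5 libraries. MX1 stands at a mean of 101.0 in control, 11972 in no contact and 26814 in contact.

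Prostaglandin, receptivity, Notch and ephrin, and stress response genes were not called as lists by camera in the fit of all 15 libraries. In contact against control, prostaglandin genes had 1 higher and 1 lower of 17 (adjusted p = 0.986). The higher one, the cyclooxygenase PTGS1, at 0.46 (limma adjusted p = 0.0412), was not called with the run as a block (0.0900) or without control 83 (0.123) or 84 (0.127), no contact 110 (0.0504) or contact 28 (0.110), 87 (0.0991) or 97 (0.108). The lower one, the prostacyclin receptor PTGIR, at -0.72 (limma adjusted p = 0.0262), was not called with the block (0.0519) or without control 24 (0.0768), 83 (0.0684) or 84 (0.0629) or contact 28 (0.0764), 87 (0.0637) or 97 (0.0731). PTGES, a prostaglandin E synthase, at -0.83, did not pass (limma adjusted p = 0.0785), but passed with the block (-0.75, 0.000121), with DESeq2 (0.0278) and without control BEEC.103 (0.0392) or BEEC.104 (0.0454), and against no contact it passed with the block (0.000532). Also in contact against control, receptivity and histotroph genes had 2 higher and 1 lower of 32 (5 and 3 adjusted over the list alone; adjusted p = 0.895), and stress response genes 1 and 1 of 23 (adjusted p = 0.213). In no contact against control the stress list (adjusted p = 0.345) was called lower without control BEEC.104 or no contact 90 (0.0399 each). Notch and ephrin genes had 3 higher and 3 lower of 28 in contact against control, with a median of -0.14 and a mean of 0.07 (adjusted p = 0.574). Adhesion genes, called as a list in no contact against control (though with adjusted p = 0.668 with an estimated correlation), had 2 higher and 4 lower of 29 in contact against control (2 and 6 adjusted over the list alone; adjusted p = 0.213). The hypoxia list, called lower in contact against control, had 2 higher and 1 lower of 32 in contact against no contact and missed the threshold (adjusted p = 0.0615). There it was called lower with the run as a block (0.0409), DESeq2 (0.0396), limma-voom (0.0392), edgeR (0.0492 and 0.0495 with different factors), a fit of the 2 groups (0.0424) and without no contact 109 (0.0161) or contact 28 (0.0140), but not with an estimated correlation (adjusted p = 0.578). In no contact against control it had adjusted p = 0.204, and was called lower without control BEEC.104 (0.0306) or no contact 30 (0.0416). PTGS2 and ESR1 did not pass in any comparison (limma adjusted p = 0.868 and 0.969 in contact against control), and PGR and OXTR were not tested. Camera called none of the marker lists in the fit of all 15 libraries. The filter kept 11 of the 20 epithelial markers measured, with EPCAM at no more than 2 reads in any library, and 17 of the 19 stromal markers. Epithelial markers had 0 of 11 members called by limma in contact against control (0 at an unadjusted p under 0.05, and 0 with DESeq2 or edgeR), stromal markers 1 higher and 1 lower of 17 (the lower one FAP, a protease of activated fibroblasts, at -0.61, limma adjusted p = 2.19e-06), endothelial and muscle markers 1 and 1 of 10, leukocyte markers 0 and 1 of 5, and embryo markers 1 and 0 of 6. With fry, which tests whether a list's genes move one way on balance, stromal markers and endothelial and muscle markers passed in this comparison (adjusted p = 0.0203 and 0.0231). The keratin KRT8 had 33592 ± 3718, 35842 ± 4706 and 34118 ± 3320 normalized counts in control, no contact and contact (SD, n = 5).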

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

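Apart from the splits, the dilution test and the split controls, the tests in this part were chosen after the results were seen. In groups of 5 libraries, 501 sets of values (162 named genes and 5 library measures) were searched for one library far from the others, and 29 were found where chance gives about 25, so single cases carry little weight. The lone library was the highest for IFIT1 (contact 28, 20070 normalized counts), IFI44L (control BEEC.104, 71.37), ND4L (contact 87, 6313), ERAP2 (no contact 109, 849.1), PSMB8 (control 84, 321.5), PTGIR (no contact 109, 37.93), MMP2 (control 24, 14150), CDH1 (contact 28, 1698) and C3 (control 24, 499300). It was also the highest for DDIT4 (control 24, 625.4), CDK1 (contact 97, 225.2), SESN2 (no contact 89, 393.5), ESRP2 (control BEEC.104, 137.3), CD68 (contact 87, 460.9), GBP1 (contact 28, 1393), MYBPH (contact 107, 98.84), HSD11B1 (contact 108, 63.68), TWIST2 (no contact 90, 132.7) and EMCN (contact 87, 48.43). It was the lowest for OAS1X (control BEEC.103, 37.58), CXCL8 (control 83, 114.3), EPHB3 (no contact 90, 315.4), PTGS2 (control 24, 789.9), ITGAV (contact 87, 2203), THBS1 (no contact 90, 12630), SESN2 (control 24, 350.1), TNFSF10 (control 83, 19.37), ITGA2 (control 83, 51.34) and EPHA4 (no contact 90, 879.2).

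For contact against control, 1 of 100 splits of the 10 libraries, the real one, called as many genes in either direction, with 901 and 726 real calls and at most 1 in another split. For contact against no contact it was again 1 of 100, with 469 and 229 against at most 107, in the split of 28, 30, 87, 89 and 90 against the rest, which follows the runs; with the run as a block the counts were 571 and 344. For no contact against control 1 of 100 splits gave as many as the 186 higher genes, and 4 of 100 gave as many as the 14 lower genes. However, another split called 179 genes one way and 152 the other, more in total than the 200 calls of the real grouping. That other split set libraries 24, 30, 83, 84 and 89 against 90, BEEC.103, BEEC.104, 109 and 110, which follows the run of library numbers except for library 90. This points to a structure of the samples by run, and with the run as a block the counts were 244 higher and 52 lower.

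MX2 had the largest step from no contact to contact among the 42 interferon-stimulated genes, at 4.89 on the log2 scale in limma against 2.95 for IFIT2, the next, and a median of 0.94. Reads shared with the paralog MX1 would keep the ratio of the 2 genes, but the median ratio was 11.7 times higher in contact, and a single library does not account for the step, since the lowest contact library had 669.8 normalized counts and the highest no contact library 85.35. The authors' deposited table gives log2 fold changes of 1.03 for MX2, 1.03 for MX1 and 1.80 for IFIT2, and its value for MX2 lies far below the step in the normalized counts of the same table, for a reason that was not tested. In no contact against control MX2 had 21 to 102 reads per library against 0 to 2, with log2 fold changes of 4.93 in limma (adjusted p = 8.44e-06), 6.07 in edgeR (0.0631) and 5.65 in limma-voom (0.163), so the calls lost there had larger folds, while DESeq2 kept the call and the authors' deposited table gives an FDR of 0.953. MX2 reads were 0.167% to 0.742% of MX1 reads in no contact. In control they were 0% in libraries 83 and BEEC.103 and at least 0.82% in the others. With 0 to 2 MX2 reads per control, these values cannot tell whether the ratio rose. Reads shared with MX1 therefore stay open as a source of the MX2 rise from control to no contact. What makes the step of MX2 from no contact to contact steeper than that of the other genes also stays open.

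The share of mitochondrial reads was lower in contact. Shallow libraries do not account for it, since the highest of the 3 deep contact libraries had 7.57% and the lowest of the other 10 libraries 8.22%. Within the runs the difference was below 0 against both groups, and the one nearest 0 was -1.52 percentage points. Leaving the genes called higher out of the total removed 6.99% of the difference from control, so dilution by induced transcripts is not the main source. No test here separates a difference in the cells from RNA handling that differed by group, and both stay open.

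A further 715 genes were called higher and 713 lower with contact but not without. Whether they are a weaker form of the same response without contact is left open for the set as a whole. With separate controls for the 2 comparisons, genes called only with contact were selected anew in each of 20 fits, 462 to 2185 of them. These sets are therefore not the same as the 715 and 713 genes. The share of them moving the same way in no contact had a median of 79.3% over the 20 fits (SD 10.4, range 50.2% to 95.3%). Their median signed log2 change in no contact had a median of 0.138 (SD 0.054, range 0.000339 to 0.211). The lowest values came when the contact group was set against controls 24, 83 and 84, and no contact against BEEC.103 and BEEC.104, that is, against different runs. The bounds written before these fits were run, over 50% and above 0 in each fit, were met on the side of a weaker response. The values did not pass these bounds in each fit by more than the SD across fits. That margin was required only after the values were seen. No control library was shared in these fits, so their values cannot come from a shared library. Separate controls of the same run, such as 83 and 84, can still deviate together. For the 715 and 713 genes, called against shared controls, both shared controls and a weaker response may contribute.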

How the results depend on the processing

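Tests with TMM factors in limma, pseudocounts of 0.5 and 5, edgeR with TMM, library weights and without libraries that stood apart were chosen after seeing the data. Over 275 values for named genes and 8242 alternatives, 7878 kept direction and side of the threshold, 293 lost and 71 gained the call, and 0 called values changed sign. Values that passed neither before nor after are counted as kept even where their sign changed, which happened in 23 alternatives of 10 genes' results and in 56 alternatives of 13 list results. For each change below the cause was not tested. Depth limits contact libraries 97 and 108 most.

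Counts moved as follows, with smaller moves left out. Genes lower in contact than control were 420 without both shallow contact libraries, and 473 to 980 with single libraries left out. Genes lower in no contact than control were 30 with DESeq2, 52 with the run as a block, 22 with library weights, 6 without the shallow libraries and no contact 90, and 3 to 19 with single libraries left out. Genes higher in contact than no contact were 306 without both shallow libraries (325 to 561). Genes lower there were 111 in a fit of the 2 groups, 344 with the block, 84 without both shallow libraries, 140 without these and no contact 90, and 115 to 349 with single libraries left out. Genes lower in both embryo comparisons were 27 with DESeq2, 43 with the block, 21 with weights, 6 without the shallow libraries and no contact 90, and 3 to 16 with single libraries left out.

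List tests lost their call as follows (adjusted p). In contact against control, the matrix list had 0.0782 with DESeq2, 0.0557 with the block, 0.0806 without both shallow libraries, 0.0855 without these and no contact 90, and 0.00999 to 0.0667 with single libraries left out, and the hypoxia list 0.0733 with DESeq2 and 0.0502 without the shallow libraries and no contact 90. With an estimated correlation the inflammatory, cell cycle and cholesterol lists had 0.135 each, matrix 0.387 and hypoxia 0.357. In no contact against control, DESeq2 gave 0.374 for the inflammatory and for the adhesion list and 0.221 for matrix, an estimated correlation 0.668 for each of them, and fry 0.288, 0.288 and 0.17. Without a filter the inflammatory list had 0.149 and adhesion 0.0787. The adhesion list had 0.0553 with limma-voom, 0.0618 and 0.0608 with edgeR under relative log expression and TMM factors, and 0.184 without the shallow libraries and no contact 90, where matrix had 0.092. Single libraries left out gave 0.00219 to 0.388 for inflammatory, 0.00355 to 0.173 for adhesion and 0.00399 to 0.116 for matrix. In contact against no contact, an estimated correlation gave 0.236 for inflammatory, 0.071 for cell cycle and 0.125 for cholesterol, and fry 0.0709 for inflammatory. Among lists not called with all libraries in no contact against control, library weights gave 0.0387 each for cell cycle, hypoxia and stress response, and leaving out the shallow libraries and no contact 90 gave 0.0306 for cell cycle and 0.0461 for stress response, all lower.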

Other observations

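Of the pluripotency genes of the early embryo, POU5F1 had 1 read over the 5 control libraries, 0 in no contact and 1 in contact, and NANOG was listed at 0. Of the 6 tested members of the embryo list, limma called SSLP1 alone, higher in contact than control (20.3 ± 3.26 and 34.5 ± 9.98 normalized counts, limma adjusted p = 0.0205). That call was lost without control 24 (0.0516) or 84 (0.0599) or contact 28 (0.0713) or 87 (0.0647). SSLP1 also rose by 0.56 in no contact against control, without being called (limma adjusted p = 0.332). In contact against no contact its log2 fold change was 0.14 (limma adjusted p = 0.724).

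Some members of the interferon, antigen presentation and inflammatory lists are listed at 0 in all libraries, among them IRF7, SAMHD1, TAP2, CXCL10 and IL1B. EPCAM, an epithelial surface marker, had 3, 4 and 1 reads over the control, no contact and contact libraries. LGALS9, a galectin of the endometrium below the filter, had 1, 21 and 90 reads.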
